A study of Mus musculus with 6 samples.

How the data were processed

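The series holds RNA sequencing of limb bone perichondrium from postnatal day 4 mice, with 3 wild-type libraries and 3 libraries from mice with a deletion of Fbn1 by Scx-Cre. Per the labels' protocols, RNA was extracted with a micro-scale column kit and libraries were made from full-length amplified cDNA (SMART-Seq v4) by transposase fragmentation, a chemistry that amplifies by PCR and does not mark strand. The deposited matrix holds whole-number counts per gene, not normalized, for 55536 genes. Per the submitters' processing notes the genome build was GRCm38.p6 and DESeq2 was used, and the DESeq2 version is not given in the sources used here. Per the file headers the count matrix carries names of coordinate-sorted alignment files, and the settings for strand and for reads with several matches are not given in the sources used here. The authors' deposited table of differential genes holds log2 fold changes of knockout against wild type, and its log base was judged from the values, 1629 of which equal log2 fold changes of a DESeq2 fit within 1e-04. Its summary columns hold 0 throughout and were not used.

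Groups were taken from the labels. Columns were matched to libraries by title, and no column of other samples was present. Gene symbols, positions, transcript GC content and transcript length came from GENCODE M21, in which 55450 gene identifiers had a symbol. Some mitochondrial genes and their nuclear copies carried almost equal counts, for example 950016 for mt-Co3 and 960035 for Gm28437 over all libraries. The pair of mt-Co1 and Gm29216 lay further apart, at 418138 and 325716. Almost equal counts would arise if reads with several matches were counted at each copy, and genes with such copies are uncertain. Because the counting is not known to use strand, reads of overlapping antisense genes cannot be told apart.

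The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, default shrinkage) in R 4.3.3, on the deposited counts with TMM scaling and the filterByExpr filter by group, which left 15712 genes, and without covariates. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size over the square root of the F statistic. CPM values are scaled by TMM, and log2 CPM values used a prior count of 2. The common biological coefficient of variation was 0.249. Total counts per library lay between 7209217 and 10316017. On simulated counts for this comparison, with 15712 genes, the procedure recovered 28% of genes changed 2-fold, 84% of those changed 4-fold, 96% at 8-fold and 100% at 16-fold, with 11 false calls. Those counts were drawn for each gene independently around 1 mean profile shared by all libraries. They lack the differences in GC trend, muscle markers and sex of the real libraries, so the shares need not hold there. Ugt8a, at 5.86-fold in the real data, had an edgeR adjusted p of 0.459. Ribosomal-like and mitochondrial genes took between 35.5% and 47.3% of counts, and Lars2 alone between 9.23% and 14.5%, which lowers the depth left for other genes. Reads carry no molecular identifiers, so counts are not independent molecules.

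Before the data were examined, 37 gene lists were written, on matrix, pathways, skeletal cell types, other cell types of the limb, stress and quality. Of these, 34 were tested. Lymphoid and epidermal markers had fewer than 5 measured members, and sex-linked genes were left out of the list tests and used to describe the libraries. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation and with fry. With the estimated correlation none of the 7 calls held, and fry called 0 lists, with an unadjusted p under 0.05 for 5 lists. The estimate was 0.82 for muscle, 0.81 for mitochondrially encoded, 0.14 for early-response and 0.09 for microfibril genes. It lay below the preset for collagen (0.00077), tendon (-0.0058) and interferon genes (-0.021), so a higher correlation does not account for the calls lost there. Each list also has a count of members past the threshold over all genes tested and adjusted over the list alone. The adjustment over a list alone does not account for the number of lists.

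The genes named were fixed by a rule before the data were examined. Fbn1 was always named, with a fixed set of genes of fibrillins, growth factors and growth plate signalling. Next came genes past the threshold with a mean log2 CPM of at least 1, non-overlapping groups and an established symbol. Where fewer than 3 passed in a direction, the 6 with the smallest unadjusted p were taken and reported as not past the threshold. From each list up to 4 members with the smallest unadjusted p were eligible, and Xist and Y-linked genes served as a check of the libraries. Values of some genes under this rule are not reported here.

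Alternatives fixed before the data were examined were RLE size factors, upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with and without sample weights, robust shrinkage, a block on the number in the titles, each library left out, covariates for muscle, erythroid and chondrocyte lists, other thresholds and other list tests. Added after seeing the data were a GC correction (a natural spline with 5 degrees of freedom of each library's log2 CPM deviation on transcript GC content, as edgeR offsets), the same with length, with the block and with each library left out, a covariate for libraries with Xist, both of those libraries left out, removal of genes on X and Y, removal of ribosomal-like and mitochondrial genes, and Fbn1 left out of its own list. Raw reads, exon-level coverage of Fbn1 and other tissues were not analysed here.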

Results

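RNA sequencing measured gene expression in perichondrium, the connective tissue sheath of cartilage, dissected from limb bones of mice at postnatal day 4. Of the 6 libraries, 3 came from wild-type mice and 3 from mice in which Fbn1 was deleted with Scx-Cre, a recombinase under the control of the scleraxis gene of tendon and ligament cells. Fbn1 encodes fibrillin-1, the main structural protein of extracellular microfibrils and the gene mutated in Marfan syndrome. The libraries are named here as in their titles, mut-596, mut-597 and mut-795 for knockout and WT-596, WT-597 and WT-795 for wild type, and the labels do not give the meaning of these numbers. Total counts were 7716609, 7209217 and 9720268 for mut-596, mut-597 and mut-795, and 9055779, 10316017 and 8019248 for WT-596, WT-597 and WT-795. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries. The single comparison asked which transcripts differ between knockout and wild-type perichondrium, and the series title points to TGFβ signalling, the growth factor pathway whose latent ligands are held on microfibrils.

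Fbn1 fell in every knockout library. It was at 7.96 ± 1.81 CPM (SD, n = 3) in knockout and 89.1 ± 28.1 CPM (SD, n = 3) in wild type, an 11.2-fold difference. The log2 fold change of knockout against wild type was -3.48 (SE 0.29), with an edgeR adjusted p of 1.03e-04. The counts behind these levels were 76, 45 and 69 in mut-596, mut-597 and mut-795, against 1255, 898 and 458 in WT-596, WT-597 and WT-795. The knockout mean was 91.1% below the wild-type mean. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 3 libraries against 3 allow. The gene (ENSMUSG00000027204) lies on the minus strand of chromosome 2 from 125300594 to 125507993 in GRCm38, and which exons were deleted is not given in the sources used here. Its edgeR adjusted p was 0.104 with a covariate for the 2 knockout libraries that contained Xist, at a log2 fold change of -3.65. That covariate, like leaving both libraries out, sets mut-795 alone against the wild types.

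**Figure D1:**
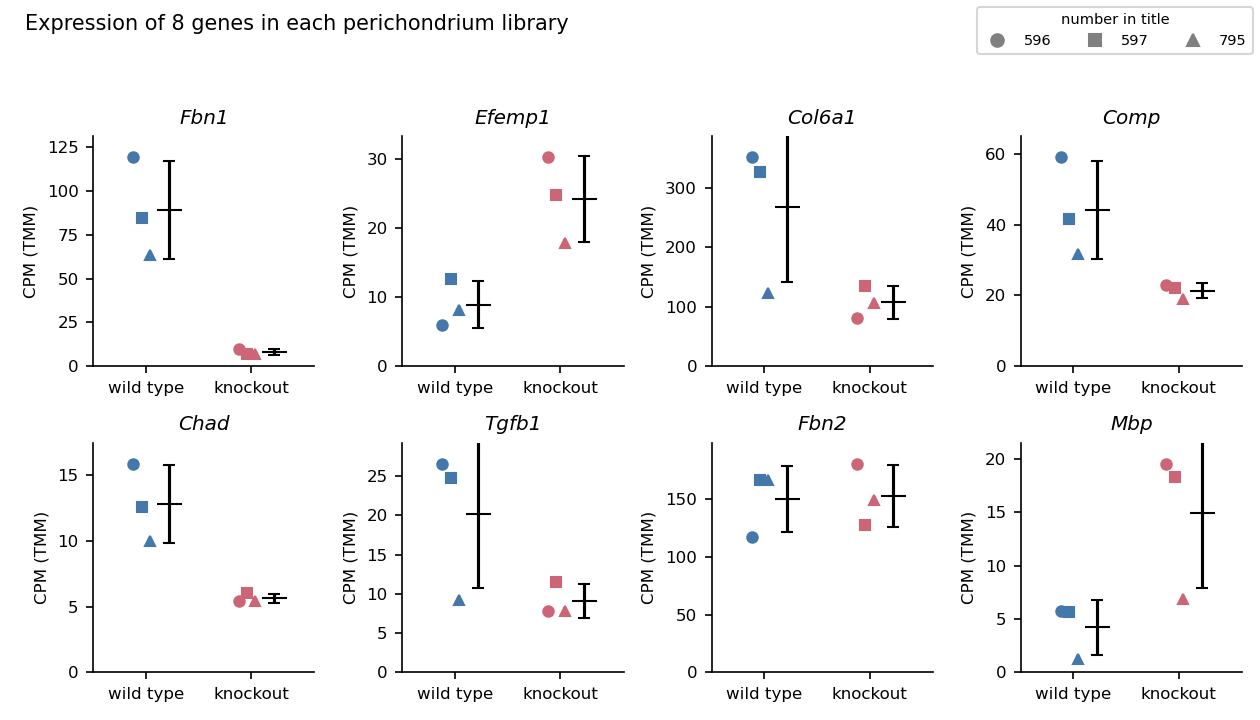
Expression of 8 genes in each library, as CPM scaled by TMM (linear axes from 0). Each symbol is 1 library, the horizontal bar is the group mean and the error bar is the SD (n = 3). Fbn1 was at most 11.3% of the wild-type mean in the knockout libraries and between 63.5 and 119 CPM in wild type, and among wild types WT-795 lay nearest to the knockouts for Col6a1, Comp, Chad and Tgfb1.

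No other gene passed the test over all 15712 genes. The 6 genes with the smallest p among those higher in all 3 knockout libraries were Efemp1, Ugt8a, Mbp, BE692007, Kdm6a and Ddx60. Efemp1, which encodes the extracellular glycoprotein fibulin-3, was at 24.3 ± 6.24 CPM in knockout and 8.90 ± 3.44 CPM in wild type (SD, n = 3), a log2 fold change of 1.44 (SE 0.30). The myelin genes Ugt8a and Mbp were at log2 fold changes of 2.55 and 1.77, the X-linked histone demethylase Kdm6a at 0.99, and the interferon-induced helicase Ddx60 at 1.49. BE692007 was at 12.1 ± 2.47 CPM in knockout and 6.01 ± 0.687 CPM in wild type (SD, n = 3). On the lower side came Nfkbib at -1.82, an inhibitor of NF-kB, the epoxide hydrolase Ephx1 at -1.87, the zinc finger gene Zfp628 at -1.95, the forkhead factor Foxp4 at -1.47 and Tmem254b at -1.34. Tmem254b shares reads with its near-identical copies Tmem254a and Tmem254c, with totals of 1590, 1646 and 1525 counts, so its value is uncertain. Each of these genes had an edgeR adjusted p of 0.459. DESeq2 called 4 genes, which were Fbn1 (adjusted p = 5.51e-28), the sex marker Xist (adjusted p = 6.80e-05), Efemp1 (adjusted p = 0.0390) and Gm44357 (adjusted p = 0.00505). Xist and Gm44357 lie outside the naming rule and are named after their values were seen.

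At an unadjusted p under 0.05, 1648 genes differed by edgeR, 529 higher and 1119 lower in knockout, where chance gives about 786. Of all genes tested, 1867 (11.9%) had non-overlapping groups, and chance gives 10% for 3 against 3. The unadjusted count was 664 without mut-596, 709 without WT-596, 676 without WT-597 and 643 with a covariate for muscle markers, each below that chance number, and 4776 without WT-795. It was 990 with the GC correction, 490 with the Xist covariate, 359 with both Xist libraries left out, 2683 with a covariate for chondrocyte markers and 3965 by limma-voom with sample weights. The lower share of the unadjusted genes was 67.9%, 74.4% with upper-quartile scaling and 54.0% with limma-voom, and there was no lean to lower genes with the sample weights (50.1%), with the chondrocyte covariate (49.0%) or without WT-795 (2388 higher and 2388 lower). Leaving out WT-795 raised the count past the adjusted threshold from 1 to 1553 genes, 676 higher and 877 lower, among them 50 named genes that had not passed before, and leaving out mut-795, the only knockout library with Ddx3y counts, raised it to 9, among them the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, all lower in knockout. These 4 are named after their values were seen. Across 11848 genes, which are not independent replicates, the log2 fold change fell with transcript GC content (Spearman rho = -0.636). The libraries also differed in sex: Xist, the transcript of the inactive X chromosome, had 6221 and 4024 counts in mut-596 and mut-597 and at most 4 elsewhere, while the Y-linked Ddx3y had 0 counts in those 2 libraries and between 842 and 1641 in the others.

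**Figure D2:**
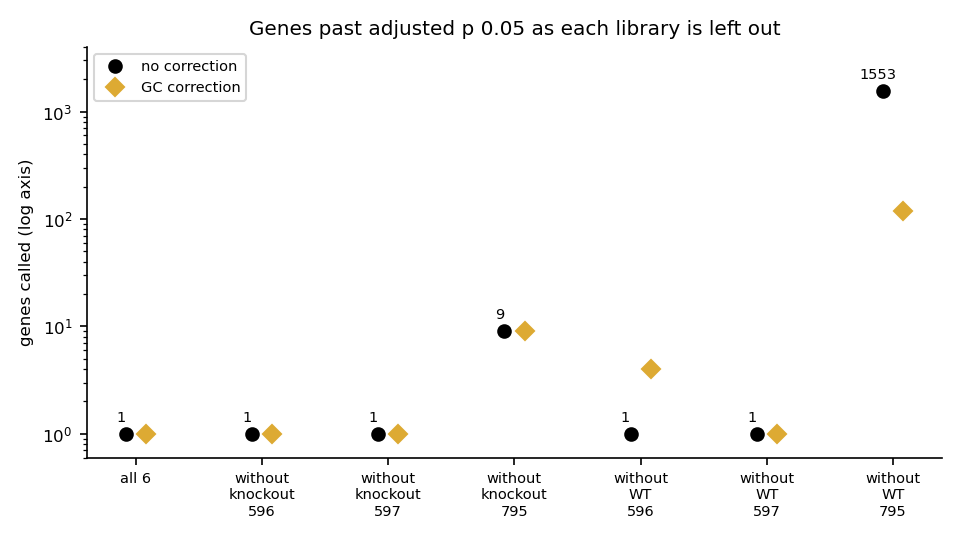
Number of genes past an edgeR adjusted p of 0.05 (log axis) with all 6 libraries and with each library left out, without and with a correction for transcript GC content. The count was 1 with all 6 libraries and 1553 without WT-795, which the GC correction lowered to 118.

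**Figure D3:**
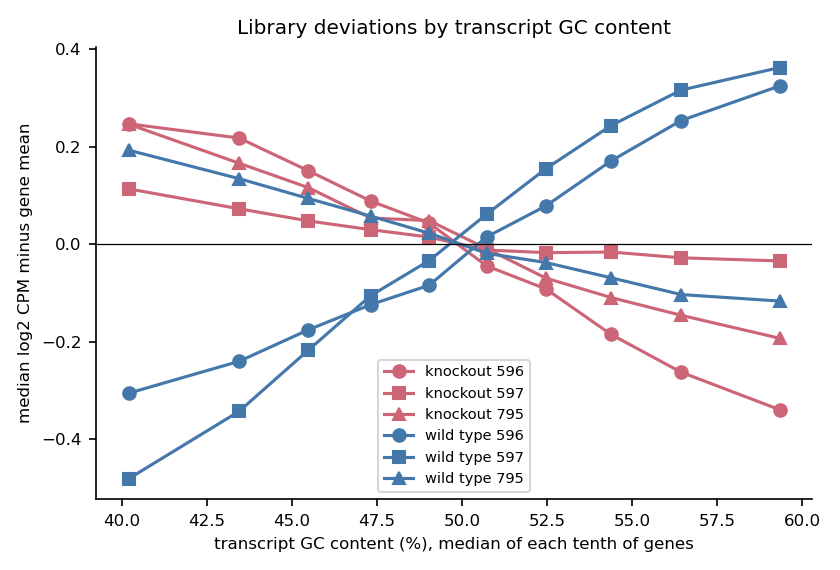
Median log2 CPM minus each gene's mean, for genes grouped by transcript GC content (percent), 1 line per library. The Spearman rho of deviation with GC content across genes was 0.53 in WT-596, 0.55 in WT-597 and between -0.48 and -0.19 in the other libraries.

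Genes of the microfibril and elastic fibre list were mostly lower in knockout, with 19 of 32 measured members below 0 and a median log2 fold change of -0.24. Adjusted over the list alone, Fbn1 fell and Efemp1 rose, while over all genes tested Fbn1 alone passed by edgeR. With the Xist covariate Efemp1 did not pass over the list (edgeR adjusted p = 0.286). Fbn2, which encodes the second fibrillin, was at 153 ± 26.7 CPM in knockout and 150 ± 28.6 CPM in wild type (SD, n = 3), a log2 fold change of 0.02 (SE 0.23) whose sign changed with upper-quartile scaling. The latent TGFβ binding protein genes Ltbp4 and Ltbp3 were at -1.21 and -0.55, and Adamtsl4, which encodes a microfibril-associated protein, at -0.94. With the GC correction Ltbp3 was at -0.14 (SE 0.17). The list was lower than other genes by limma camera (adjusted p = 0.0369), and the adjusted p was 0.816 with an estimated correlation. Without Fbn1 itself the list had a camera adjusted p of 0.132 and a median of -0.18, and the GC correction gave 0.593. The microfibril call also ended without mut-795 (camera adjusted p = 0.145), WT-596 (0.105) or WT-795 (0.0652, with a larger median of -0.35), and with the chondrocyte covariate (0.0579).

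Neither list on TGFβ passed the set test. Among 25 pathway components, 14 lay above 0 and 11 below. Their median log2 fold change was 0.11, while their mean was -0.10 and camera pointed down (adjusted p = 0.718). The ligand genes Tgfb1 and Tgfb3 were at -1.17 (SE 0.35) and -0.70 (SE 0.24), Tgfb2 at 0.13 and the receptor gene Tgfbr2 at 0.16, and Itgb8, whose integrin activates latent TGFβ, was at 0.77. Tgfb1 was at 9.05 ± 2.16 CPM in knockout and 20.2 ± 9.50 CPM in wild type (SD, n = 3), with WT-795 at 9.28 CPM inside the knockout range. Of 32 TGFβ-responsive genes, 18 lay below 0 with a median of -0.08 (camera adjusted p = 0.240). Tgfb1i1, Tgfbi and Acta2 were at -1.01, -0.63 and -0.84, and the widely used response gene Ccn2 at -0.37. No member of either list passed by edgeR, over all genes or adjusted over the list alone. Without WT-795, 5 of the pathway components and 4 of the responsive genes passed by edgeR over all genes tested, 1 of them higher in each list. With mut-795 alone against the wild types the responsive list had a camera adjusted p of 0.0466 (Xist covariate) or 0.0493 (both Xist libraries left out), 2 fits of the same comparison, and the pathway component list stayed uncalled.

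Collagen genes were lower in knockout on balance. In the list of fibrillar collagens and collagen processing, 20 of 33 members lay below 0, the median log2 fold change was -0.16 and camera called the list (adjusted p = 0.0462, and adjusted p = 0.479 with an estimated correlation). Col6a1 and Col6a2, which encode chains of the beaded-filament collagen VI, fell when adjusted over the list alone, at -1.32 (SE 0.34) and -1.19 (SE 0.30), and no member passed over all genes tested. Over the list alone both calls ended with the GC correction (edgeR adjusted p = 0.0704 for each), and without mut-596 (0.160), mut-795 (0.154), WT-596 (0.202) or WT-597 (0.0835). Col6a1 was at 107 ± 27.7 CPM in knockout and 267 ± 126 CPM in wild type (SD, n = 3), with WT-795 at 122 CPM inside the knockout range. The small proteoglycan gene Bgn was at -0.82 and Pcolce, an enhancer of procollagen processing, at -0.69. Of 28 matrix proteases and inhibitors, 16 lay above 0 (median 0.04, mean -0.05, camera down, adjusted p = 0.865), Mmp2 fell at -1.23 when adjusted over the list alone, and Adamts5 was at 0.77. The Mmp2 call ended with the GC correction (edgeR adjusted p = 0.0638 over the list) and with any 1 library other than WT-795 left out (0.106 to 0.249). The collagen call ended with the GC correction (camera adjusted p = 0.139), the chondrocyte covariate (0.0806) and the replicate block (0.0532), and with any 1 library other than WT-597 left out (0.0509 to 0.131). It also ended without genes of chromosomes X and Y (0.0913) and without ribosomal-like and mitochondrial genes (0.0546), and it stayed with mut-795 alone against the wild types (0.0283 with the Xist covariate, 0.0356 with both Xist libraries left out).

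Tendon and ligament genes were lower in knockout, with 17 of 25 members below 0 and a median of -0.36. Comp and Chad, both cartilage and tendon matrix genes, fell when adjusted over the list alone. Comp was at 21.4 ± 2.06 CPM in knockout and 44.1 ± 13.9 CPM in wild type (SD, n = 3), a log2 fold change of -1.05 (SE 0.25), and Chad at -1.19 (SE 0.27). Neither passed over all genes tested. Over the list alone both calls ended with the GC correction (edgeR adjusted p = 0.134 for Comp and 0.0782 for Chad, at -0.62 and -0.84), and without mut-597 (0.0559), mut-795 (0.0855) or WT-596 (0.117). Fmod, a collagen-binding proteoglycan gene, was at -0.72, the transcription factor gene Egr1 at -0.94 and Scx, whose promoter drives the Cre, at -0.66. The list had a camera adjusted p of 0.0369, and adjusted p = 0.479 with an estimated correlation. It was not called after the GC correction (0.139), without mut-597 (0.106) or without WT-795 (0.109), where the median was larger at -0.45. Nor was it called with the chondrocyte covariate (0.0579), or with mut-795 alone against the wild types (0.155 with the Xist covariate, 0.150 with both Xist libraries left out).

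Markers of the skeletal cell types other than tendon and ligament were not called as lists. The 30 perichondrium and periosteum genes had a median of -0.06 (camera adjusted p = 0.648), with Clec3b at -1.02. Among 27 chondrocyte genes, 15 lay above 0 (median 0.07, mean -0.06, camera down, adjusted p = 0.679), Comp and Chad were those that fell when adjusted over the list alone, and Acan, the main cartilage proteoglycan gene, was at -0.54. These calls ended with the GC correction (edgeR adjusted p = 0.144 and 0.0845 over the list), and without mut-597 (0.0603), mut-795 (0.0923) or WT-596 (0.127). Without WT-795 the chondrocyte list had a median of 0.23 and camera pointed up (adjusted p = 0.527). Hypertrophic chondrocyte, osteoblast and osteoclast lists had medians of -0.21, -0.23 and -0.13 and camera adjusted p of 0.256, 0.256 and 0.561. The osteoblast gene Ifitm5 was at -1.07.

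Growth plate signalling genes did not pass by edgeR. Pthlh, the ligand that holds chondrocytes in proliferation, was at -0.40 (SE 0.32), the hedgehog target genes Ptch1 and Gli1 at 0.46 (SE 0.30) and -0.12 (SE 0.26), and Fgf18, a perichondrial growth factor, at -0.75 (SE 0.41). The sign of Gli1 changed with the GC correction, to 0.25. Of 39 BMP and GDF genes, 28 lay above 0 with a median of 0.14. Id4, Bmp5, Inhba and Gdf11 were at 0.91, 0.63, 0.54 and 0.59. That list had a camera adjusted p of 0.0722, and 0.00894 after the GC correction (adjusted p = 0.718 with an estimated correlation). It was also called with the stricter filter (0.0462) and without mut-795 (0.0464) or WT-596 (0.0416), and with the GC correction it was not called without mut-596, mut-597 or WT-597 (0.0506 to 0.0755). Camera adjusted p was 0.370 for hedgehog, 0.708 for WNT, 0.932 for FGF, 0.340 for IGF and growth hormone, 0.831 for Notch, and 0.370 for retinoic acid and prostaglandin genes. Their medians were -0.12, -0.06, 0.08, -0.15, -0.10 and -0.02, and Wnt9a, Spry4, Flrt2, Igf2, Igfbp6, Jag1, Crabp1 and Rara were at -0.82, -0.60, 0.59, -1.25, -1.02, 0.60, -0.91 and -1.04. For FGF genes the mean was -0.00352, on the opposite side of 0 from the median.

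In the immediate early and heat shock list, 25 of 32 members were below 0 with a median of -0.28 (camera adjusted p = 0.0271, and adjusted p = 0.816 with an estimated correlation). Jund and Atf3, transcription factor genes of the early response, fell when adjusted over the list alone, at -1.52 and -1.69, and neither passed there with any 1 library other than WT-795 left out (edgeR adjusted p = 0.0858 to 0.142). In the interferon list, 14 of 19 members were above 0 with a median of 0.40 (camera adjusted p = 0.0369, and adjusted p = 0.479 with an estimated correlation), and the RNA sensor genes Ifih1 and Ddx58 and the interferon-induced Xaf1 were at 1.27, 0.69 and 0.81. The early-response list had a camera adjusted p of 0.557 after the GC correction, 0.0985 without mut-795, 0.134 without WT-597, the library with the highest muscle list median, and 0.120 with the muscle covariate. The interferon call ended without mut-597 (0.106), mut-795 (0.0654), WT-597 (0.0510) or WT-795 (0.109), with the chondrocyte covariate (0.0579), by DESeq2 (0.0502) and by limma-voom without or with sample weights (0.0733 and 0.126). It stayed after the GC correction (camera adjusted p = 0.0273, and adjusted p = 0.718 with an estimated correlation). With that correction it ended without any of the same libraries (camera adjusted p = 0.0501 to 0.219).

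Skeletal muscle genes were lower in knockout, with 36 of 38 members below 0 and a median of -0.68 (camera adjusted p = 1.06e-04, and adjusted p = 0.816 with an estimated correlation). Actn2 and Des, which encode proteins of the muscle Z-disc, were at -1.39 and -1.42. The list medians of single libraries overlapped between the groups, at -1.26, -0.17 and -0.33 in mut-596, mut-597 and mut-795 and -0.19, 0.94 and -0.78 in WT-596, WT-597 and WT-795, relative to the wild-type mean. The muscle call ended without WT-597 (camera adjusted p = 0.565) or mut-596 (0.0525). All 13 mitochondrially encoded genes were above 0 with a median of 0.54 (camera adjusted p = 1.06e-04, and adjusted p = 0.816 with an estimated correlation), mt-Nd3 at 0.65. None passed adjusted over the list alone, WT-795 had a list median of 0.60 beside 0.61 in mut-795, and the GC correction gave a camera adjusted p of 0.184. Without WT-795 the median was 0.88, and 10 of the 13 passed by edgeR over all genes tested, all higher.

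Among other cell types, genes of mast cells and of myelin differed within lists that were not called. Adjusted over the list alone, the mast cell protease genes Tpsb2, Cma1 and Mcpt4 fell, at -1.27, -0.91 and -0.74, and the neutrophil genes S100a8 and S100a9 rose, at 0.98 and 0.78, in a list of 9 measured genes where Tpsb2 was at 27.2 CPM in WT-795 and 31.8 CPM in mut-597 (camera adjusted p = 0.648, median 0.00, mean -0.02). S100a9 lies outside the naming rule and was chosen after its value was seen. Its groups overlapped, at 13.9 CPM in mut-597 and 18.0 CPM in WT-597. The calls of S100a8 and S100a9 ended with the GC correction (edgeR adjusted p = 0.158 over the list), and all 5 calls ended without mut-596, mut-795 or WT-596 (0.0565 to 0.469). Without mut-597 the Cma1 and Mcpt4 calls ended (0.0558 and 0.124), without WT-597 that of Mcpt4 (0.0846), and without WT-795 those of S100a8 and S100a9 (0.0894 and 0.0940). In the Schwann cell and nerve list of 13 genes, the myelin genes Mal and Mbp were among those that rose adjusted over the list alone, at 1.71 and 1.77 (camera adjusted p = 0.256, and 0.0111 after the GC correction, where adjusted p = 0.718 with an estimated correlation). Without the correction, neither passed over the list without mut-596 (edgeR adjusted p = 0.248 and 0.119) or without mut-597 (0.0648 for each). Nor did they with the Xist covariate, which sets mut-795 alone against the wild types and where Mal turned to -0.21. Mal also did not pass without WT-596 (0.0938) or WT-795 (0.0685), where Mbp did. Des, Ndufa4l2 and Smtn, members of the pericyte and smooth muscle list, fell adjusted over the list alone, at -1.42, -1.34 and -1.17 (camera adjusted p = 0.256). Those 3 calls ended with the GC correction (edgeR adjusted p = 0.106 over the list), where the list median went from -0.15 to 0.083, and without mut-596, mut-795, WT-596 or WT-597 (0.135 to 0.348). Plvap of endothelium was at -1.16 and the macrophage genes Cd68 and Mrc1 at -1.35 and 0.64, with camera adjusted p of 0.132 and 0.679 for their lists. Over all genes tested none of these passed by edgeR.

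**Figure D4:**
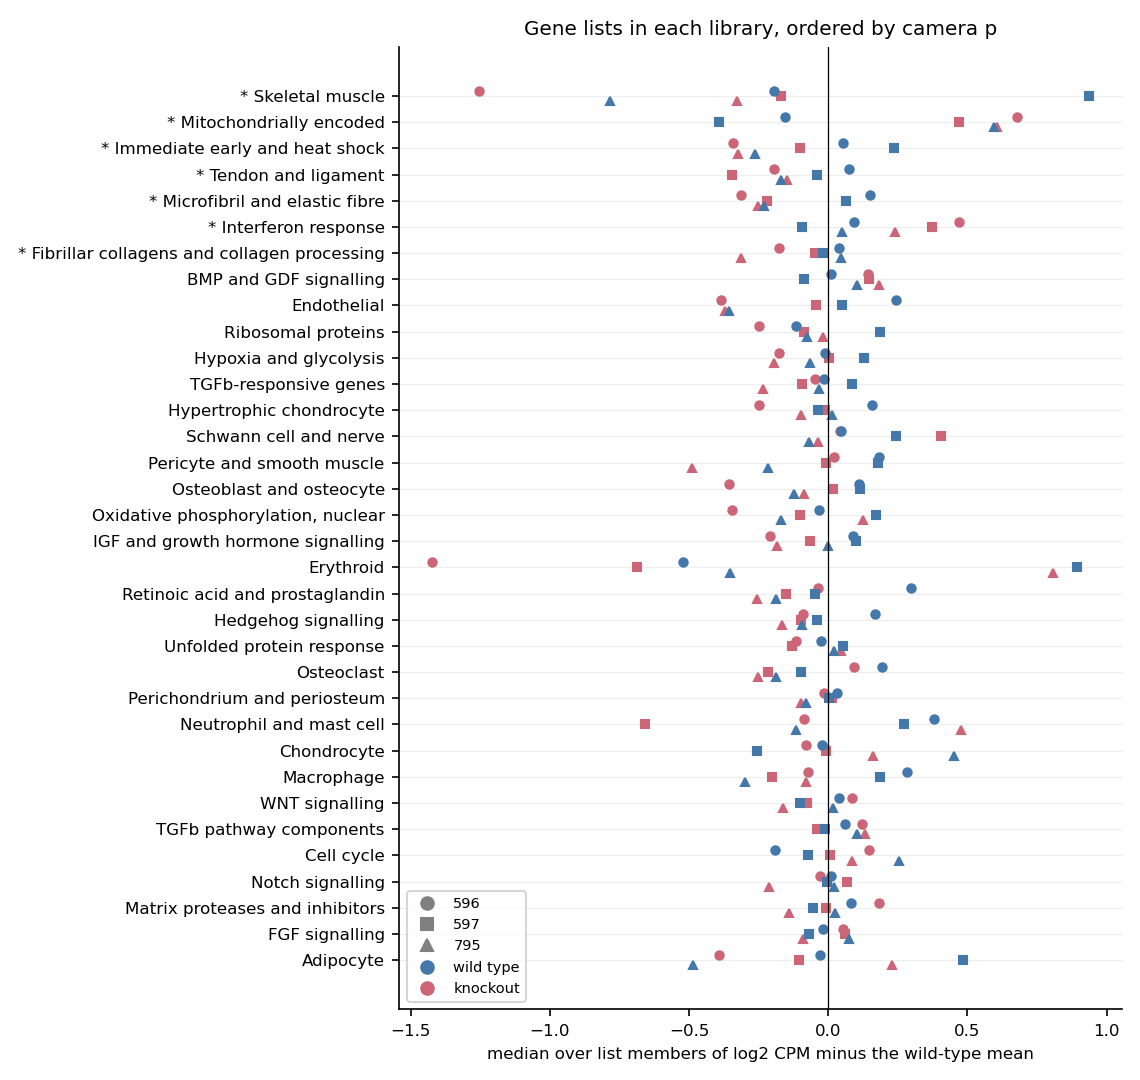
Median over the members of each of 34 gene lists of log2 CPM minus the wild-type mean, 1 symbol per library, with lists ordered by camera p. Asterisks mark the 7 lists past a camera adjusted p of 0.05. WT-795 lies among the knockouts for mitochondrially encoded genes (0.60) and for microfibril genes (-0.23).

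The authors' deposited table lists 1643 genes, 529 higher and 1114 lower in knockout. Of these, 1630 matched a gene of the count matrix, and 1629 fold changes equalled those of a DESeq2 fit of the deposited counts within 1e-04. In that fit 1629 of the listed genes had an unadjusted p under 0.05, and 4 had an adjusted p under 0.05. In the authors' deposited table Fbn1 is at -3.50, Tgfb1 at -1.18, Col6a1 at -1.33 and Efemp1 at 1.44. All 1465 listed genes that edgeR tested had the same direction there. The table was made from the same counts and is not independent of the fits above. After the GC correction 593 of the listed genes had an edgeR unadjusted p under 0.05.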

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

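Chosen only after the result was seen were the tests of GC content, of a wrong label for WT-795 and of sex, and the alternatives with the GC correction, while the splits of the libraries were planned before. Xist is outside the genes the comparison tested and stood far above its level in wild type in 2 knockout libraries, at 806 CPM without TMM scaling in mut-596 and 558 in mut-597, against at most 0.442 in the wild types. The 3 wild types and mut-795 had Ddx3y counts and these 2 libraries had 0, so genotype and sex overlap in part, and genotype can be compared at 1 sex only between mut-795 and the wild types.

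The first pattern is the lean of unadjusted differences to lower expression in knockout, 1119 of 1648 genes. Lower genes in the authors' deposited table had a median transcript GC content of 56.1%, against 42.5% for those higher. A GC trend between libraries that does not need the genotype was present among wild types alone. WT-795 minus the mean of WT-596 and WT-597 gave a Spearman rho of -0.577 with GC content across genes. That value cannot decide the cause of the lean, because the trend between the groups moved genes in both directions. The median log2 fold change was 0.38 in the 1185 genes of lowest GC content and -0.41 in the 1185 of highest. With the GC correction 618 of 990 unadjusted genes (62.4%) were still lower, against 67.9% without it. The lean was absent by limma-voom with sample weights (50.1% lower), with the chondrocyte covariate (49.0%) and without WT-795 (2388 of 4776). Without WT-795 the wild types left were those whose deviations rose with GC content (rho 0.53 and 0.55), yet no lean was seen. What part of the lean, if any, the GC trend accounts for cannot be told from these values. A genotype effect on GC-rich genes was not separately tested and stays open.

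The second pattern is the 1553 genes past the threshold without WT-795, where all 6 libraries gave 1. A knockout mislabelled as WT-795 is argued against, since its Fbn1 level was 6.32 times the highest knockout library. With the GC correction and without WT-795, 118 genes still passed, 109 of them among the 1553. Whether the GC trend is the whole cause cannot be told, because a correction by transcript GC content can leave part of such a trend. Across genes WT-795 lay nearer to the knockouts, with Spearman correlations of log2 CPM of 0.967, 0.976 and 0.974 to mut-596, mut-597 and mut-795. Its correlations to WT-596 and WT-597 were 0.947 and 0.927. WT-795 also stood apart in its chondrocyte list median, 0.45 above the wild-type mean where the other libraries lay between -0.25 and 0.16. Its share of ribosomal-like and mitochondrial counts was 47.3%, against 35.5% and 37.3% in WT-596 and WT-597. In mut-596, mut-597 and mut-795 that share was 44.6%, 46.5% and 37.6%. Its limma-voom sample weight, fitted to these same data, was the lowest (0.43, others 0.67 to 2.27). What set WT-795 apart stays open. With all 6 libraries, 3 of the 10 splits into 3 and 3, the real one included, gave at least as many genes as the real one (1 gene, highest other 2). Also, 10 splits are too few for a share under 0.05. The 3 splits that join WT-795 to 2 knockouts each called 0 genes by edgeR and gave 3124, 3094 and 772 unadjusted genes, 2 above and 1 below the 1648 of the real split.

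The third pattern is the lower collagen and tendon lists in knockout. Sex and genotype cannot be told apart for either list, because mut-795 is the only knockout library without Xist signal: its median relative to wild type was -0.32 for collagens, below the wild types (-0.02 to 0.04) and the mean of -0.11 of the Xist libraries, and -0.15 for tendon genes, inside the wild-type range of -0.17 to 0.08, where the Xist libraries averaged -0.27. After the GC correction the collagen median went from -0.16 (bootstrap SE 0.14 over members) to -0.093 (SE 0.065) and the tendon median from -0.36 (SE 0.18) to -0.21 (SE 0.10), so both calls ended with medians nearer 0 and no wider spread. The GC trend and a genotype effect cannot be told apart for either list. The collagen shift left is within 2 SE of 0, but this SE measures spread over genes of the same libraries, not between libraries, and cannot decide it. The corrected collagen medians of the knockouts (-0.17 to -0.028) stayed below the wild types (-0.0058 to 0.034). The corrected tendon medians of single libraries, -0.075 in mut-596, -0.21 in mut-597 and 0.032 in mut-795, overlap those of the wild types (-0.11 to -0.0099). Chance also stays open: 4 of 10 splits, the real one included, called at least as many lists as the real one (7 lists, highest other 8). Also, 10 splits are too few for a share under 0.05.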

How the results depend on the processing

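The GC correction, the Xist settings, the removal of X and Y genes or of ribosomal-like and mitochondrial genes, and Fbn1 left out of its list were chosen after seeing the data, and the rest were planned. Fbn1 was lower in each of 31 alternatives, between -3.74 and -3.11 on the log2 scale, and past the threshold in 29. Fbn1 was at -3.65 with the Xist covariate (edgeR adjusted p = 0.104) and at -3.65 with both Xist libraries left out (edgeR adjusted p = 0.0905). Both settings rest on mut-795 alone against the wild types, a lone knockout assumed to vary like the other libraries, so they are 1 comparison fitted in 2 ways, and both called 0 genes by edgeR (490 and 359 unadjusted). Without a low-count filter edgeR called 270 genes (33 higher, 237 lower), DESeq2 4 (3 higher, 1 lower, with 4 in the authors' deposited table against 1 for edgeR), and the GC correction with the replicate block 4 (3 higher). The other fits with all libraries called Fbn1 alone. Leaving out 1 library gave 1 to 1553 genes (0 to 676 higher, 1 to 877 lower). With the GC correction as well, it gave 9 without mut-795 (4 higher, 5 lower), 4 without WT-596 (3 higher), 118 without WT-795 (33 higher, 85 lower) and 1 otherwise. The cause was not tested except for the explanations weighed for WT-795. Without mut-795, 4 of the 5 lower genes are Y-linked, and the other 2 knockouts have 0 to 3 counts of each.

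Lists called numbered 10 in both Xist settings, 9 with the stricter low-count filter, 3 with the chondrocyte covariate, where the microfibril, collagen, tendon and interferon calls ended, 4 with the GC correction, with GC and length, and with the GC correction and the block, and 0 with an estimated correlation (before or after GC correction) or fry, against 7 as reported. Leaving Fbn1 out of its own list gave 5, the microfibril and collagen lists being lost. The collagen list does not hold Fbn1 and kept its members, so its call ended through the adjustment over lists. Leaving out 1 library gave 3 to 7 lists. With the GC correction as well, it gave 1 without mut-596 or mut-597, 6 without mut-795, 4 without WT-596, 3 without WT-597 and 2 without WT-795. Lists that changed sign with a call in either fit were Erythroid with the Xist covariate (camera adjusted p = 4.5e-04) and with both Xist libraries left out (camera adjusted p = 9.7e-05), Notch signalling with the GC correction without mut-795 (camera adjusted p = 0.0495) and Skeletal muscle with the GC correction without WT-597 (camera adjusted p = 0.677). Over all alternatives the 7 called lists ranged in camera adjusted p from 2.3e-07 to 0.997. Lists uncalled in both fits changed sign in 154 of 1053 values. The cause was not tested.

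The numbers in the titles did not pair the libraries, with correlations of deviations of -0.18, 0.24 and -0.20 between mut-596 and WT-596, mut-597 and WT-597, and mut-795 and WT-795, and of the knockouts only mut-597 correlated best with its own number. With the replicate block 1 gene and 6 lists were called, and the collagen list had a camera adjusted p of 0.0532. Of 2289 values of 74 named genes, 2166 kept direction and side of the threshold and 100 passed newly, 50 of these without WT-795. The 23 changes of sign belong to 4 uncalled genes. Fbn2 was at -0.0084 with upper-quartile scaling, -0.024 with the muscle covariate and -0.012 in both Xist settings, at -0.13 to 0.13 over libraries left out, and with the GC correction at -0.090 without mut-596 and -0.096 without WT-596. Tgfb2 was at -0.024 to 0.24 over libraries left out, and with the GC correction at -0.0031 without mut-597 and -0.098 without WT-596. Gli1 was at 0.25 with the GC correction, 0.29 with GC and length, 0.25 with GC and the block, and -0.25 to 0.030 over libraries left out. With the GC correction and mut-596, mut-597, mut-795, WT-596, WT-597 or WT-795 left out it was at 0.18, 0.33, 0.24, 0.32, 0.19 and 0.24. Mal was at -0.21 in both Xist settings. Of the genes reported as passing over a list alone, Fbn1, S100a8 and S100a9 passed there in both Xist settings and the others in neither. The cause was not tested. What depth alone limits was not tested. At these library sizes, a simulation without the GC and sex differences between the libraries recovered 28% of 2-fold changes.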

Other observations

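The groups and the X-linked genes described here were picked after their values were seen, and no test beyond those already given was run on them. The myelin genes Mbp, Mal and Ugt8a differed between the knockout libraries. Without the GC correction, the medians of the Schwann cell and nerve list did not follow them. Those medians were 0.04, 0.41 and -0.04 in mut-596, mut-597 and mut-795, and 0.05, 0.24 and -0.07 in WT-596, WT-597 and WT-795. After the GC correction they were 0.46, 0.46 and 0.095 in the knockouts and -0.058, 0.33 and -0.099 in the wild types, in the same order. There mut-596 and mut-597, the libraries with Xist, lay above mut-795 and the wild types. Mbp was at 19.5, 18.3 and 6.89 CPM in mut-596, mut-597 and mut-795, and at 5.79, 5.66 and 1.25 CPM in WT-596, WT-597 and WT-795. Mal was at 8.06, 6.15 and 1.34 CPM in knockout and at most 1.90 in wild type, and Ugt8a at 6.60, 7.50 and 1.44 CPM against at most 1.11.

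Of 57 measured genes of replication-dependent histones, 13 were above 0 and the median log2 fold change was -0.21, yet 7 of the 11 with an edgeR unadjusted p under 0.05 were higher in knockout. Hist1h2aj was at 71.8 and 72.4 CPM in mut-596 and mut-597, the libraries with Xist, at 8.85 in mut-795 and at 6.93 to 12.3 in wild type. Hist1h2an, Hist1h2ai, Hist1h2af, Hist1h2ah and Hist1h2ad were at log2 fold changes of 1.20, 1.03, 1.05, 0.90 and 0.72, and for each of these 6 genes mut-795 lay inside the wild-type range. These genes have near-identical copies whose reads may be shared, which was not examined, so their values are uncertain. After the GC correction the median of the 57 was 0.06.

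Among X-linked genes known to escape inactivation, Kdm6a was at 36.6 and 25.8 CPM without TMM scaling in the libraries with Xist, 19.6 in mut-795 and at most 16.3 in wild type. Kdm5c was at 14.6 and 13.4 CPM against 9.29 in mut-795 and 11.3 to 12.8 in wild type. Ddx3x and Eif2s3x were above the wild types in all 3 knockout libraries, at 452 to 519 CPM against 197 to 399, and 38.0 to 43.9 CPM against 25.0 to 32.5. Erythroid genes varied more between libraries than between groups, with list medians from -1.42 in mut-596 to 0.89 in WT-597, and haemoglobin genes took 0.454% to 3.49% of counts. The first principal component held 52.3% of the variance and placed WT-596 and WT-597 on one side and the other 4 libraries on the other. The remaining lists had camera adjusted p of 0.227 for ribosomal proteins, 0.240 for hypoxia and glycolysis, 0.340 for nuclear oxidative phosphorylation, 0.370 for erythroid genes, 0.370 for the unfolded protein response, 0.821 for the cell cycle and 0.979 for adipocyte genes. Their medians were -0.09, -0.21, -0.03, -0.34, -0.13, 0.04 and -0.06, and Eno1 of glycolysis, which shares reads with its copy Eno1b, was at -1.32.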
